A study of Arabidopsis thaliana with 10 samples.

How the data were processed

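Total RNA was measured in roots of Arabidopsis thaliana, wild type (WT, Col) and the mutant bts-3, after 2 weeks of growth followed by 3 days (72 h) with iron (+Fe) or without it (-Fe). The 4 groups held 2 arrays each for WT and 3 each for bts-3, and per the labels these were biological replicates. Per the labels' protocols, 100 ng of RNA was labelled for each Affymetrix array.

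The deposited values were log2 expression values, 1 per probe set and array. They were made with RMA in Affymetrix Expression Console, per the submitters' processing notes, and no version, background value or detection call was given in the sources used here. RMA subtracts background, sets all arrays to a common distribution and summarises the probes of a probe set, so a transcript near background has a compressed fold change. The values ran from 0.713 to 14.1, and array medians lay between 5.27 and 5.45. For arrays, their number limits the precision.

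The table held 28583 probe sets. The platform annotation used here paired 16722 of them with exactly 1 gene and 759 with several genes, and left 11102 unnamed. Of the single-gene probe sets, 16574 were matched by gene ID to the RefSeq table of assembly TAIR10.1, from which only names were taken. The sources used here name no genome build for the array, so no coordinates are given. The 17481 probe sets with at least 1 gene were tested, without a filter on dim values.

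Group means of all 10 arrays were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that groups of 2 shared the estimate of the spread with groups of 3. The fit had 6 residual degrees of freedom, to which eBayes added 4.57 prior ones. There were 5 comparisons, all two-sided: -Fe against +Fe within each genotype, bts-3 against WT on each medium, and the difference of the iron responses (interaction). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Values after ± are standard deviations (SD) for levels, and each fold change has its standard error (SE).

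The comparisons, the tests, 19 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took, per comparison, up to 10 single-gene probe sets with the highest and 10 with the lowest fold change among called ones whose arrays did not overlap between the groups (5 and 5 for the interaction, with no condition on overlap). BTS, BTSL1, BTSL2 and members of the lists were named besides. BTS has no named probe set here, so the mutant labels were not checked by its transcript. The lists held 232 loci, of which 37 (15.9%) had a named probe set. With 3 or more named genes, 6 lists were tested as sets. For 8 lists with 1 or 2 named genes only values are given, and 5 lists (iron storage, phosphate starvation, endodermis, vascular tissue, wounding) were not analysed here.

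Because so few loci were named, 17 more lists were written after the annotation had been read and before any test was run. They were 14 families picked by gene symbol, the chloroplast-encoded genes, the mitochondrion-encoded genes (too few named to test), and a list of loci taken from general knowledge of iron deficiency, 20 of them measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 30 tests for the first lists and 80 for the added ones. Camera with the correlation estimated per list and fry were run as alternatives. Members were also adjusted over the list alone with limma p-values.

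Whether replicate numbers pair samples was checked from the deviations from group means. In bts-3, same-numbered +Fe and -Fe arrays correlated at r = 0.302, 0.511 and 0.389 across probe sets. Arrays of unlike number correlated at -0.292 to -0.113. As deviations within a group are tied to one another, these values are not independent. The numbers therefore appear to pair the bts-3 samples, on the evidence of the values and not of the labels. The WT numbers gave r = -0.107 and did not, so crossed WT numbers were tried as an alternative. Between the genotypes, same-numbered arrays correlated at 0.303 and 0.261 on -Fe and at -0.0289 and -0.0723 on +Fe (replicates 1 and 2).

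The fit was tested on simulated data with 200 changed genes among 17481. For WT -Fe against +Fe it recovered 20.9% of changes of 1, 86.6% of 2 and 97% of 3 on the log2 scale. For the interaction the shares were 13.4%, 55.2% and 83.3%. The simulation gave each gene 1 spread in all 4 groups. In the data the root iron uptake gene S8H had SDs of 0.12 and 0.02 on WT +Fe and -Fe. On bts-3 +Fe and -Fe its SDs were 0.89 and 2.43. Its log2 fold change of 6.19 in WT was not called, so these shares do not describe genes with such unequal spread. Camera at the preset correlation called 5 of 100 unchanged simulated lists at an unadjusted p under 0.05, in genes simulated as independent. The correlation estimated from the data was 0.95 for the root iron uptake list, 0.757 for iron-deficiency signalling and 0.705 for the added iron-deficiency loci. The simulation therefore says nothing about camera p-values at the preset correlation for lists so correlated.

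Alternatives covered a second quantile normalization, centring of arrays, filters on dim probe sets, the rows tested, the spread model, array weights, thresholds, replicate blocks, fits of 2 groups alone and leaving out each array. Figures were drawn with matplotlib 3.10.9.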

Results

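Gene expression was measured on 10 arrays of root RNA from Arabidopsis thaliana. The mutant bts-3 is named for BRUTUS (BTS), known as an E3 ubiquitin ligase that restrains the iron-deficiency response, and the labels do not state the lesion. WT and bts-3 plants had been moved for 3 days to medium with or without iron, with 2 arrays per medium for WT and 3 for bts-3. Arrays of 1 group correlated with their group mates at a mean r between 0.969 and 0.991, and the lowest value belonged to bts-3 -Fe replicate 1. That array also stood apart on the first principal component (29.4% of the variance), at 42, beside the WT -Fe arrays at 44.2 and 22.1, whereas the other bts-3 -Fe arrays lay at -14.7 and -26.7.

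The first comparison asked how WT roots responded to iron deficiency. All 30 measured genes of the 3 iron lists had higher means on -Fe, with a median log2 fold change of 2.68, and 1 of them passed over all genes. The camera calls of the 3 lists, given below, were lost at adjusted p = 0.292, 0.292 and 0.424 with an estimated correlation. BHLH101, a basic helix-loop-helix factor induced by iron shortage, rose from 3.31 ± 0.23 to 7.77 ± 0.01 (SD, n = 2 each), a log2 fold change of 4.46 (SE 0.54, limma adjusted p = 0.0378). AT5G41280 rose by 1.80 (SE 0.21). AT3G13840 fell by 1.99 (SE 0.21), AT2G03260 fell by 1.82 (SE 0.24) and AT1G15540 fell by 1.75 (SE 0.22). These 5 were the called probe sets of the 17481 tested, 2 higher and 3 lower.

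The root iron uptake list had 4 measured members of 22, and all 4 rose in WT when adjusted over the list alone, while none passed over all genes. The SE and the calls used a spread pooled over all 10 arrays, including bts-3. The SD of the list mean was 0.009 on WT +Fe and 0.007 on WT -Fe. It was 0.835 on bts-3 +Fe and 1.714 on bts-3 -Fe. A missing call over all genes in WT therefore also reflects the spread in bts-3. S8H, an enzyme of fraxetin synthesis, had a log2 fold change of 6.19 (SE 1.14), the metal transporter MTP8 of 5.70 (SE 1.02), BGLU42, a beta-glucosidase acting on coumarins, of 4.34 (SE 0.86), and COSY, coumarin synthase, of 1.11 (SE 0.43). So the measured members were 3 genes of coumarin metabolism and 1 transporter of manganese, and the iron transporter IRT1 and the reductase FRO2 were not analysed here. The median log2 fold change of the list was 5.02, with a camera adjusted p of 2.85e-07 and an adjusted p = 0.292 with an estimated correlation.

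All 6 measured members of 19 in the list of iron-deficiency signalling rose when adjusted over the list alone, and BHLH101 alone over all genes. The short peptide genes IMA2 and IMA1 had log2 fold changes of 4.32 (SE 0.89) and 2.92 (SE 0.84). BTSL1 and BTSL2, the BTS-like ligases, had values of 2.40 (SE 0.41) and 1.95 (SE 0.48), and the regulator PYE of 0.92 (SE 0.31). The list median was 2.66 (camera adjusted p = 1.9e-10, adjusted p = 0.292 with an estimated correlation). Of the 20 measured loci of the added iron-deficiency list, 17 rose when adjusted over the list alone and none over all genes, among them AT1G52120 with a log2 fold change of 5.97 (SE 0.97) and AT5G38820 with 5.17 (SE 0.93). That list had a median of 2.49 (camera adjusted p = 3.07e-22, adjusted p = 0.424 with an estimated correlation).

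In the zinc homeostasis list, 2 of 4 measured members rose in WT on -Fe when adjusted over the list alone, the transporter gene ZIP9 by 1.99 (SE 0.45) and the regulator BZIP19 by 0.76 (SE 0.28), with no call for the list (camera adjusted p = 0.101). HCT, of the phenylpropanoid pathway, was the only measured member of its list and had a log2 fold change of 1.14 (SE 0.38). For a list of 1 gene the adjustment over the list alone leaves the limma p unadjusted (0.0126). HCT did not pass over all genes (limma adjusted p = 0.433). The shoot markers RCA and LHCB4.1 had log2 fold changes of -1.42 (SE 0.37) and -0.94 (SE 0.40), both past the threshold over the list alone and neither over all genes. Their mean level was 7.79 ± 0.34 on WT +Fe and 6.61 ± 0.28 on WT -Fe (SD, n = 2 each). The 5 measured upstream bHLH regulators, among them ILR3, and the 4 measured genes of iron-sulfur assembly and iron enzymes had no member past the threshold, with camera adjusted p of 0.886 and 0.313. The reference genes GAPC2, SAND and TIP41 had log2 fold changes of 0.08, -0.02 and 0.11.

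The count of 5 was 80 with the replicate block, 64 with the block within genotype, 106 (88 higher, 18 lower, all 5 among them) with a block in bts-3 alone, chosen after the data were seen, 157 when only the 4 WT arrays were fitted, and 0 at an adjusted p under 0.01. With all 28583 probe sets it was 4, with AT5G41280 and AT3G13840 kept and BHLH101 at an adjusted p of 0.0533. It was 0 without any 1 of the 4 WT arrays, bts-3 +Fe replicate 1 or bts-3 -Fe replicate 2, 3 and 2 without bts-3 +Fe replicates 2 and 3, and 88 and 60 without bts-3 -Fe replicates 1 and 3.

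**Figure D1:**
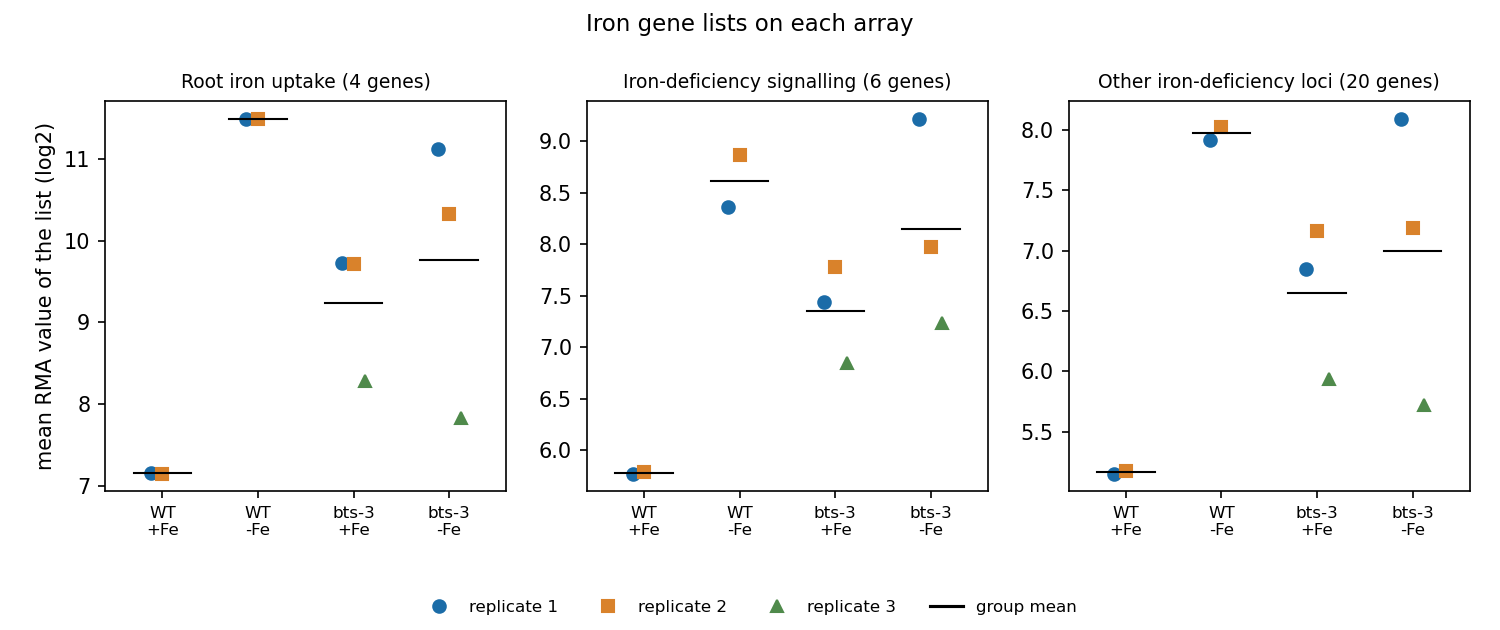
Mean RMA value (log2) of 3 iron gene lists on each of the 10 arrays, by group, with 1 point per array and a line at the group mean; the vertical axes differ in range and do not start at 0. In the root iron uptake list the WT arrays lie near 7.16 on +Fe and 11.49 on -Fe, and the bts-3 -Fe arrays spread from 7.84 to 11.12.

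The second comparison asked how bts-3 roots responded to the same treatment. The called probe sets were 4, all lower on -Fe. AT5G07610 fell from 7.05 ± 0.24 to 4.36 ± 0.13 (SD, n = 3 each), by 2.69 on the log2 scale (SE 0.18, limma adjusted p = 0.000332). AT1G12890 fell by 2.28 (SE 0.24), AT4G01870 fell by 2.16 (SE 0.25) and AT4G38410, a dehydrin family gene, fell by 1.64 (SE 0.17). No iron list gene passed over all genes.

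None of the 4 root iron uptake genes passed the threshold over the list alone in bts-3. The median log2 fold change was 0.45 (camera adjusted p = 0.429, adjusted p = 0.854 with an estimated correlation), and it was called at an adjusted p of 0.0473 with the replicate block, of 0.0403 with the later block in bts-3 alone and of 1.44e-05 without bts-3 -Fe replicate 3. The median was -0.02 without bts-3 -Fe replicate 1, 0.22 and 1.54 without bts-3 -Fe replicates 2 and 3, and 0.74 and 0.06 without bts-3 +Fe replicates 2 and 3. Per array, the list mean was 9.73 on +Fe and 11.12 on -Fe in replicate 1, 9.72 and 10.33 in replicate 2, and 8.28 and 7.84 in replicate 3. The iron-deficiency signalling list had a median of 0.30 (camera adjusted p = 0.0363, adjusted p = 0.625 with an estimated correlation), with no member past the threshold over the list alone. Its camera adjusted p was 0.0113 with the replicate block and 0.00881 with the later block in bts-3 alone. The list mean was 7.44 on +Fe and 9.22 on -Fe in replicate 1, 7.78 and 7.97 in replicate 2, and 6.84 and 7.24 in replicate 3. BTSL1 had a log2 fold change of 0.21 (SE 0.34) and BTSL2 of 0.37 (SE 0.39). The call of the signalling list was lost without bts-3 -Fe replicate 1 (median -0.003, adjusted p = 0.87), bts-3 -Fe replicate 2 (0.072) or bts-3 +Fe replicate 3 (median 0.06, adjusted p = 0.646). Its median was 0.61 without bts-3 +Fe replicate 2 and 0.74 without bts-3 -Fe replicate 3. Of the 20 other iron-deficiency loci, AT2G14247 rose by 2.83 (SE 0.69) and AT1G73120 fell by 1.95 (SE 0.52) when adjusted over the list alone (list median 0.21, camera adjusted p = 0.218). The stress gene GSTU25, a glutathione transferase, had a log2 fold change of -1.94 (SE 0.55), past the threshold over its list of 2 alone. The other member, ZAT10, had a value of -0.83 (SE 0.80) and did not pass.

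The mean of the 2 shoot markers was 6.50 on bts-3 -Fe replicate 1, and 7.19 and 7.53 on replicates 2 and 3, against 7.45 ± 0.04 on bts-3 +Fe (SD, n = 3). The count of 4 was 17 with the replicate block, 26 with the block within genotype, 44 (25 higher, 19 lower) with the later block in bts-3 alone, and 1 when only the bts-3 arrays were fitted without it. It was 1 without bts-3 +Fe replicate 1 or bts-3 -Fe replicate 2, 18 without bts-3 -Fe replicate 1, and 8 and 13 without bts-3 +Fe replicates 2 and 3.

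The third comparison asked what the mutation changed with iron present. It gave 47 called probe sets, 23 higher and 24 lower in bts-3. AT3G01345 had the highest fold change, from 3.75 ± 0.23 in WT (SD, n = 2) to 10.66 ± 0.27 in bts-3 (SD, n = 3), a log2 fold change of 6.91 (SE 0.86, limma adjusted p = 0.0126). Also higher were AT1G65500 by 4.08 (SE 0.38), AT1G73120 by 4.06 (SE 0.58), BHLH101 by 3.71 (SE 0.50) and AT5G39120 by 3.49 (SE 0.31). The others of the 10 highest were AT5G52390 (3.29), the glutathione transferase GSTF3 (3.24), the subtilase SBT3.3 (3.08), AT1G07885 (2.87) and AT5G07610 (2.64).

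The cold-regulated gene COR15A had the lowest fold change among the called genes, at 7.81 ± 0.29 in WT (SD, n = 2) and 4.85 ± 0.37 in bts-3 (SD, n = 3), a log2 fold change of -2.96 (SE 0.25, limma adjusted p = 0.00115). AT2G41810 followed at -2.89 (SE 0.33), AT3G13840 at -2.32 (SE 0.19), AT1G52790 at -2.19 (SE 0.21) and AT4G29450 at -2.19 (SE 0.34). The remaining 5 were AT4G22650 (-2.16), AT3G19320 (-2.13), AT3G18450 (-2.13), AT5G42610 (-2.06) and AT1G15540 (-1.96). In the order given, the log2 fold changes on WT -Fe against +Fe were -1.89, -1.48, -1.99, -1.59, -1.37, -1.51, 0.27, 0.30, -0.86 and -1.75. Only AT3G13840 and AT1G15540 among them were called there. For bts-3 against WT on -Fe the values were -1.39, -0.98, 0.11, -0.27, -0.17, -0.07, -0.36, -0.74, 0.41 and -0.15. The WT +Fe arrays enter both the first and the third comparison.

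**Figure D2:**
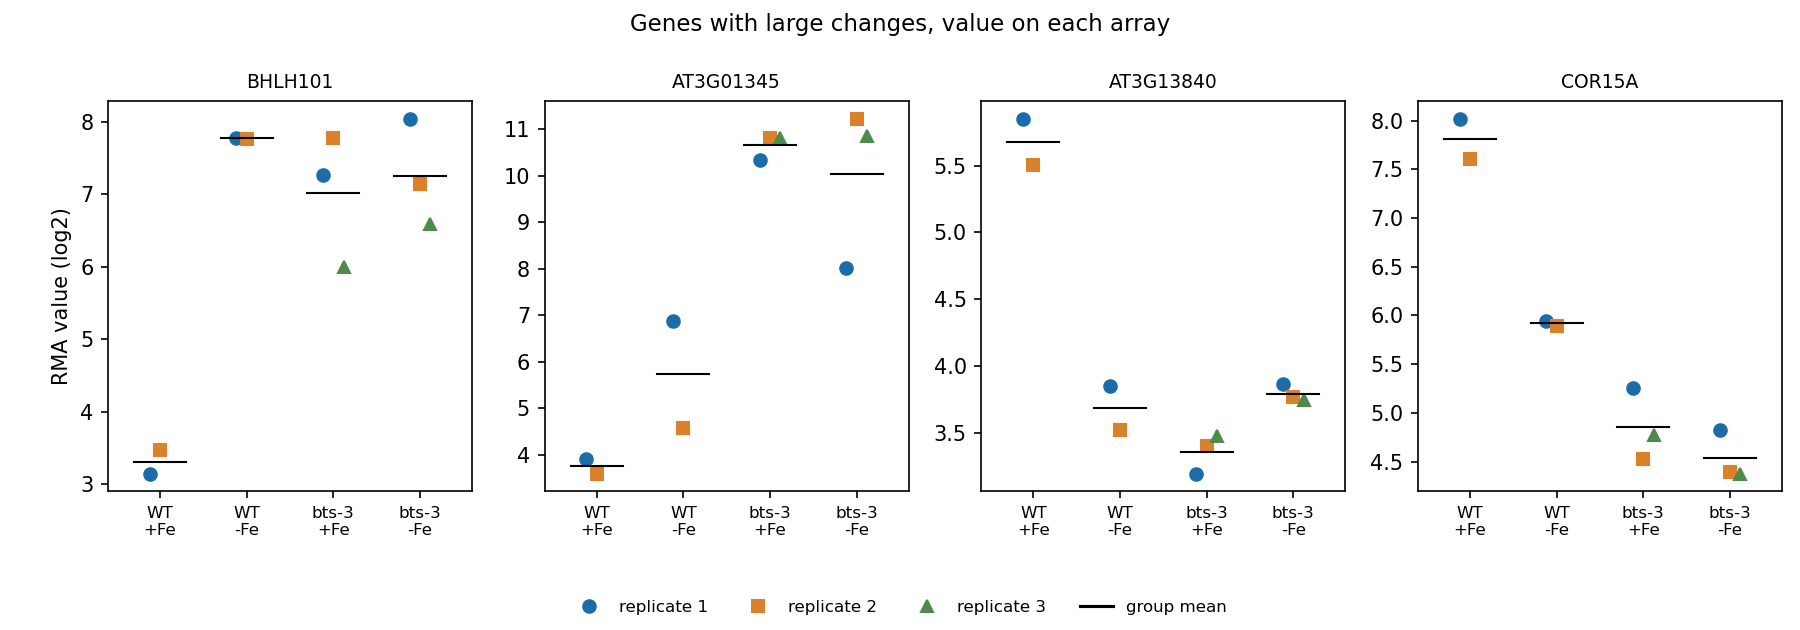
RMA value (log2) of BHLH101, AT3G01345, AT3G13840 and COR15A on each of the 10 arrays, by group, with 1 point per array and a line at the group mean; the vertical axes differ in range and do not start at 0. AT3G01345 lies at 3.59 and 3.91 on the WT +Fe arrays and above 10 on the bts-3 +Fe arrays, and bts-3 -Fe replicate 1 lies below the other bts-3 arrays. For this gene WT -Fe replicate 1 lies at 6.88, above the other WT arrays.

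Of the 30 measured iron genes, 27 had higher means in bts-3 than in WT on +Fe, and BHLH101 and AT1G73120 passed over all genes. In the signalling list, BHLH101 and BTSL1 (log2 fold change 1.57, SE 0.38) passed the threshold over the list alone, BTSL2 had a value of 0.87 (SE 0.43), and all 6 values were positive. The list median was 1.22 (camera adjusted p = 2.61e-06, adjusted p = 0.334 with an estimated correlation). In the uptake list S8H passed over the list alone, at 4.27 (SE 1.04), and COSY had a value of 0.04 (SE 0.39). Its median was 2.02 (camera adjusted p = 0.00556, adjusted p = 0.441 with an estimated correlation), and the camera p was 0.0677 without bts-3 +Fe replicate 2. Of the other iron-deficiency loci, 9 of 20 rose when adjusted over the list alone and 1, AT1G73120, over all genes (median 1.20, camera adjusted p = 7.19e-09, adjusted p = 0.468 with an estimated correlation). GSTU25 had a log2 fold change of 2.17 (SE 0.62) and BZIP23, a regulator of zinc uptake, of 0.77 (SE 0.22), each past the threshold over its list alone and not over all genes. ZAT10, listed with GSTU25, had a value of -0.26 (SE 0.89) and did not pass. The camera adjusted p of the zinc list was 0.08, and 0.441 with an estimated correlation. At the preset correlation it was 0.0164 with the replicate block, and 0.0379, 0.0408 and 0.0478 without bts-3 +Fe replicate 1, bts-3 +Fe replicate 3 and bts-3 -Fe replicate 1. The root hair markers EXPA7 and EXPA18 had values of -0.65 (SE 0.28) and -0.95 (SE 0.45) and did not pass.

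The count of 47 was 118 (76 higher, 42 lower) with the replicate block, 48 without the dimmest 25% of probe sets, 26 without all below the median level, 279 with array weights, 101 when only the +Fe arrays were fitted, and 8 at an adjusted p under 0.01. It was 6 and 4 without WT +Fe replicates 1 and 2, 10 without bts-3 +Fe replicate 1, and 93 and 73 without bts-3 -Fe replicates 1 and 3.

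The fourth comparison asked what the mutation changed without iron. No probe set was called with limma (smallest adjusted p = 0.295), and 1163 had an unadjusted p under 0.05 where chance gives 874. The count was 8 without bts-3 -Fe replicate 1 and 0 without any 1 of the other arrays. All 4 uptake genes had lower means in bts-3, with values from -0.83 (COSY, SE 0.39) to -2.49 (MTP8, SE 0.93), and none passed over the list alone. Their median was -1.80 (camera adjusted p = 0.00322, adjusted p = 0.441 with an estimated correlation), and it was -0.63 without bts-3 -Fe replicate 3 and -0.96 with the replicate block. The signalling list had a median of -0.47 (camera adjusted p = 0.15), and it was -0.96 (adjusted p = 0.00161) without bts-3 -Fe replicate 1, -0.08 (0.979) without bts-3 -Fe replicate 3, -0.25 (0.712) without WT -Fe replicate 2 and -0.05 (0.615) with the replicate block. BTSL1 and BTSL2 had values of -0.63 (SE 0.38) and -0.72 (SE 0.43). The other iron-deficiency loci had a median of -0.90, with all 20 values negative and no member past the threshold over the list alone (camera adjusted p = 2.04e-06, adjusted p = 0.519 with an estimated correlation). BZIP23 had a log2 fold change of 0.77 (SE 0.22), past the threshold over the list alone. The root hair markers EXPA7 and EXPA18 had values of -0.62 (SE 0.28) and -0.56 (SE 0.45). The shoot markers RCA and LHCB4.1 had values of 0.41 (SE 0.33) and 0.52 (SE 0.37). None of these markers passed over its list alone.

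The fifth comparison tested whether the iron response differed between the genotypes. AT3G13840 was the 1 called probe set. It was 5.68 ± 0.25 on WT +Fe and 3.69 ± 0.23 on WT -Fe (SD, n = 2 each), and 3.36 ± 0.15 and 3.79 ± 0.07 in bts-3 (SD, n = 3 each), so that its response differed by 2.43 (SE 0.27, limma adjusted p = 0.0499). Its level on bts-3 +Fe was already below that on WT -Fe and near the lower quartiles of the bts-3 +Fe arrays (2.92 to 3.05). Whether a floor limited its fall in bts-3 was not tested. Over all genes 779 probe sets had an unadjusted p under 0.05, where chance gives 874.

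All 30 measured iron genes had a smaller response in bts-3 by their values, and none passed over all genes. In the uptake list S8H, MTP8 and BGLU42 passed over the list alone, with differences of -6.09 (SE 1.47), -4.61 (SE 1.32) and -3.70 (SE 1.11), and COSY did not (-0.87, SE 0.56). The list median was -4.15 (camera adjusted p = 2.61e-06, adjusted p = 0.292 with an estimated correlation). In the signalling list BHLH101 (-4.22, SE 0.70) and BTSL1 (-2.20, SE 0.53) passed over the list alone, BTSL2 had a value of -1.59 (SE 0.61), and the median was -1.89 (camera adjusted p = 2.1e-07, adjusted p = 0.292 with an estimated correlation). Of the other iron-deficiency loci 10 of 20 passed in the same direction over the list alone, led by AT1G52120 at -6.20 (SE 1.26), with a median of -1.98 (camera adjusted p = 4.83e-18, adjusted p = 0.424 with an estimated correlation). ZIP9 had a difference of -1.78 (SE 0.59), past the threshold over its list alone. The 2 shoot markers had positive differences with a median of 0.81, and 52 of the 63 chloroplast-encoded genes had positive values, with a median of 0.17 (camera adjusted p = 0.0029, adjusted p = 0.712 with an estimated correlation).

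The call of AT3G13840 was lost when values were normalized again (0 called), and the count was 18 (2 higher, 16 lower) with the replicate block, 9 (1 higher, 8 lower) with the block within genotype and 35 (10 higher, 25 lower) with the later block in bts-3 alone. It was 0 without any 1 of the WT arrays, bts-3 +Fe replicate 1 or bts-3 -Fe replicates 2 and 3, 7 without bts-3 +Fe replicate 3 and 3 without bts-3 -Fe replicate 1. Without bts-3 +Fe replicate 2 it was 1, another gene, and AT3G13840 was not called.

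**Figure D3:**
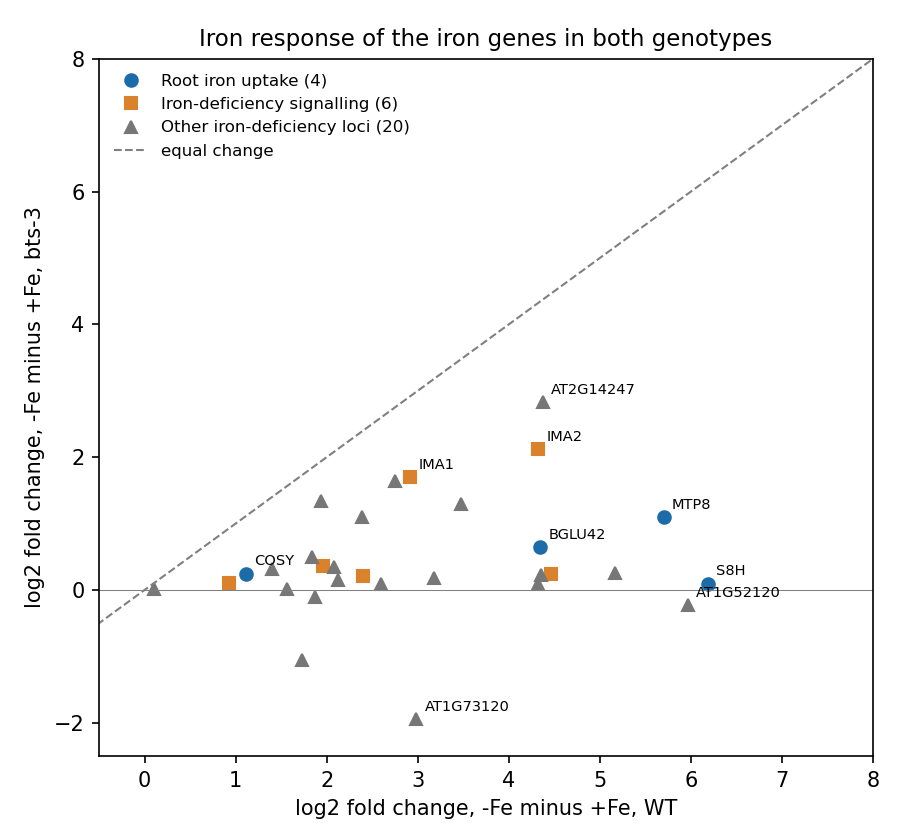
Log2 fold change on -Fe against +Fe in bts-3 (vertical axis) against that in WT (horizontal axis) for the 30 measured genes of the 3 iron lists, with 1 point per gene and a dashed line of equal change. All 30 points lie below the line.

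The iron responses of the genotypes shared no called probe set with limma, with 5 called in WT and 4 in bts-3 (1463 and 867 at an unadjusted p under 0.05). As bts-3 had no higher call and 0.000686 shared lower calls are given by independent lists, a test of this overlap holds no information. They shared 3 with the replicate block, 2 with the block within genotype and 4 with the later block in bts-3 alone, all higher. Whether bts-3 on +Fe resembled iron-deficient WT was then asked by the overlap of the third comparison with the first. BHLH101 was higher in both, and AT3G13840 and AT1G15540 were lower in both, where independent lists would share 0.00263 and 0.00412. Both comparisons use the WT +Fe arrays. In draws of noise on all arrays, with the WT +Fe group shared, the mean number of shared calls was 0.03 over 100 draws, of which 11 made any call. Among as many top probe sets as were called, taken whether or not they passed the threshold, the simulated mean was 1.86, and 27 of 100 draws shared 3 or more. The covariance of the fold changes was 0.0714, and 0.0578 in the simulation, and the correlation was 0.398 against 0.547. The 2 WT +Fe arrays were not split between the comparisons, so part of the overlap may come from them. The overlap was 30 with the replicate block and 24 with array weights, 0 without any 1 of the WT arrays, bts-3 +Fe replicate 1 or bts-3 -Fe replicate 2, and 10 and 14 without bts-3 -Fe replicates 1 and 3.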

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

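In this part the tests of a raised level on +Fe, of saturation, of 1 array alone, of a WT sample in place of the mutant, of mixed WT tissue and of as many top probe sets were chosen only after the result was seen.

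The iron response differed between WT and bts-3 by the test of the difference itself for 1 gene and 7 lists. AT3G13840 differed by 2.43 on the log2 scale, with its bts-3 +Fe level of 3.36 already below its WT -Fe level of 3.69. The median differences were -4.15 for root iron uptake, -1.89 for iron-deficiency signalling and -1.98 for the other iron-deficiency loci. They were -0.18 for UDP-glycosyltransferases, 0.37 for the trichome birefringence-like (TBL) family, 0.48 for tubulins and 0.17 for chloroplast-encoded genes. With the replicate block the adjusted p of the UDP-glycosyltransferases was 0.0643, past the threshold no longer. With an estimated correlation none of the 7 list calls was kept, the smallest adjusted p being 0.292.

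In the 30 genes of the iron lists the median difference of the responses was -2.09, and all 30 lay below 0. Saturation, which would act on each array by itself, is argued against in bts-3 -Fe replicates 2 and 3, since 27 of the 30 genes lay below both WT -Fe arrays on both, and stays open in replicate 1, where 12 did. A single bts-3 array as the whole source is argued against, since the median nearest to 0 was -1.599 when each bts-3 array was left out. A raised level on +Fe with the WT level reached on -Fe cannot be told apart from a weaker response, because the median difference from WT on -Fe was -0.856 overall but -0.025 in replicate 1, -0.682 in replicate 2 and -1.861 in replicate 3. A biological effect of the mutation stays open with it, as a hypothesis.

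The array of bts-3 -Fe replicate 1 lay near the WT -Fe arrays, with r = 0.983 and 0.98 to these and 0.971 and 0.968 to the other bts-3 -Fe arrays. A WT sample in its place is argued against by 25 genes that separated the genotypes on the other arrays, of which 21 lay on the mutant side, with a median share of 0.711 of the mutant difference kept. When replicates 2 and 3 were held out in the same way the shares were 1.036 and 0.943. Some WT tissue mixed into the sample cannot be told apart from a stronger iron response of these plants, since in 16 genes high in the mutant the median linear share was 0.471 (quartiles 0.223 and 0.726). This array and the WT -Fe arrays also had the lowest medians and the highest lower quartiles of all arrays, and an effect of the arrays themselves was not tested. Same-numbered WT and bts-3 arrays correlated in their deviations at 0.303 and 0.261 on -Fe (replicates 1 and 2), at -0.0289 and -0.0723 on +Fe, and WT +Fe and -Fe at -0.107, so a condition shared by number was not seen on +Fe or within WT, and the pair of values on -Fe rests on 1 difference of 2 WT arrays.

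AT3G13840 and AT1G15540 were lower than WT +Fe both on WT -Fe and in bts-3 on +Fe. AT3G13840 was at 5.85 and 5.51 on the WT +Fe arrays, and AT1G15540 at 5.07 and 4.78. On WT -Fe AT3G13840 was at 3.85 and 3.52, and AT1G15540 at 3.31 and 3.04. In 29 of 100 draws of noise on all arrays, as many probe sets were lower in both among as many top ones. Those top probe sets were taken whether or not they passed the threshold, so the draws do not decide whether the shared WT +Fe arrays gave the overlap. The test by called probe sets gave 0 of 100 draws, but only 11 draws made any call, so it decides nothing. An effect of the mutation that resembles iron deficiency stays open, and more WT +Fe arrays would be needed to part them.

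The 4 probe sets called in bts-3 -Fe against +Fe stood beside 7 in the highest other of the 10 splits of the 6 bts-3 arrays, where 2 splits gave as many, the real one included. These 10 splits are too few for a share under 0.05. Of the 4 splits that part all 3 replicate pairs, the highest other gave 0, and the split with 7 kept a replicate pair together.

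In probe sets with no gene name here, a fit of all 28583 called 2 in WT -Fe against +Fe (1 higher, 1 lower, beside 2 of the 5 named calls, with BHLH101 at an adjusted p of 0.0533), 6 in bts-3 -Fe against +Fe (2 higher, 4 lower) and 34 in bts-3 against WT on +Fe (18 higher, 16 lower). Probe set 13334405 was at 8.69 on WT +Fe and 13.03 on WT -Fe, and probe set 13522914 at 5.27 and 3.06.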

How the results depend on the processing

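In this part the replicate block in bts-3 only, the fit without both bts-3 arrays of number 3 and the block with crossed WT numbers were chosen only after the data were seen. Where a result changed, the cause was not tested, except that a stricter threshold can only lower a count. Replicate blocks and left-out bts-3 arrays do not alter the fold changes of WT -Fe against +Fe. The WT median of the uptake list stayed at 5.02 with the replicate block and without both bts-3 arrays of number 3. There the WT count changed through the estimate of the spread and its degrees of freedom. Of 644 values of the named genes under the alternatives other than stricter thresholds, 521 kept direction and call, 123 lost the call and 0 reversed. These genes were chosen as the largest called changes on the same arrays, so the lack of a reversal says little. Of 332 values of the other lists fixed beforehand, 327 kept their side of the threshold and 5, all of the zinc list in bts-3 against WT on +Fe, passed it. The added lists were run with an estimated correlation, with fry, with the replicate block and with the block in bts-3 only. With the replicate block the adjusted p rose past 0.05 for the xyloglucan endotransglucosylases on +Fe (0.137), the serine carboxypeptidase-like genes on +Fe (0.0644) and in bts-3 (0.0544) and the UDP-glycosyltransferases for the difference (0.0643), the last 2 of which were at 0.0553 with the block in bts-3 only, and it was 0.0415 for the ubiquitin-conjugating enzymes on +Fe. The dimmest 25% of probe sets, or all below the median level, were left out. RMA values carry no measure of signal over background here, so changes near background are limited in size.

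For WT -Fe against +Fe (5 called), the count was 3 with arrays centred on their medians (2 higher, 1 lower), which moved the median of all probe sets to 0.12, 5 without the dimmest 25% and 3 without those below the median level, 9 with trend and robust, 4 with all probe sets (2 of the 5 kept, BHLH101 at an adjusted p of 0.0533), 101 with array weights, 0 at an adjusted p under 0.01 and 157 with the WT arrays alone. It was 80 with the replicate block, 64 with the block within genotype, 106 with the block in bts-3 only, 92 with crossed WT numbers as block and 77 without both bts-3 arrays of number 3. Leaving out 1 array gave 0 to 88, the latter without bts-3 -Fe replicate 1, with 60 without bts-3 -Fe replicate 3, 3 and 2 without bts-3 +Fe replicates 2 and 3, and 0 without any 1 of the others.

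For bts-3 -Fe against +Fe (4 called), the count was 4 without the dimmest 25% and 1 without those below the median level, 10 with all probe sets, 7 with trend and robust, 10 with array weights and 1 with the bts-3 arrays alone. It was 17 with the replicate block, 26 with the block within genotype, 44 with the block in bts-3 only, 35 with crossed WT numbers and 12 without both arrays of number 3. Leaving out 1 array gave 1 to 18: 18 without bts-3 -Fe replicate 1, 1 without bts-3 -Fe replicate 2 or bts-3 +Fe replicate 1, and 8 and 13 without bts-3 +Fe replicates 2 and 3.

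For bts-3 against WT on +Fe (47 called), the count was 48 without the dimmest 25% and 26 without those below the median level, 78 with all probe sets, 279 with array weights, 8 at an adjusted p under 0.01, 118 with the replicate block, 80 without both arrays of number 3 and 101 with the +Fe arrays alone. Leaving out 1 array gave 4 to 93: 6 and 4 without WT +Fe replicates 1 and 2, 10 without bts-3 +Fe replicate 1, and 93 and 73 without bts-3 -Fe replicates 1 and 3. On -Fe (0 called with limma, 1163 at an unadjusted p under 0.05) the range was 0 to 8, with 8 without bts-3 -Fe replicate 1.

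For the difference of the iron responses (1 called), the count was 0 with quantile normalization again, arrays centred, either filter on dim probe sets, all probe sets, trend and robust, or an adjusted p under 0.01 (limma, 779 at an unadjusted p under 0.05 in the fit as reported). It was 3 with array weights, 18 with the replicate block, 9 with the block within genotype, 35 with the block in bts-3 only, 20 with crossed WT numbers and 17 without both arrays of number 3. Leaving out 1 array gave 0 to 7: 7 without bts-3 +Fe replicate 3, 1 without bts-3 +Fe replicate 2 (another gene, with AT3G13840 not called), 3 without bts-3 -Fe replicate 1 and 0 without any 1 of the others.

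The iron responses shared 0 called probe sets, and 3 with the replicate block, 2 with the block within genotype, 4 with the block in bts-3 only and 3 with crossed WT numbers. The overlap of the mutation on +Fe with the WT iron response (3) was 3 without the dimmest 25% and 1 without those below the median level, 24 with array weights, 0 at an adjusted p under 0.01, 30 with the replicate block and 27 without both arrays of number 3. With all probe sets it was again 3, but BHLH101 and AT1G15540 were not among these. Leaving out 1 array gave 0 to 14: 14 and 10 without bts-3 -Fe replicates 3 and 1, and 0 without any 1 of the WT arrays, bts-3 +Fe replicate 1 or bts-3 -Fe replicate 2.

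The camera calls of the uptake list had, with an estimated correlation and with fry, adjusted p of 0.292 and 0.153 in WT, 0.441 and 0.405 on +Fe, 0.441 and 0.405 on -Fe, and 0.292 and 0.329 for the difference. Those of the signalling list were 0.292 and 0.132 in WT, 0.625 and 0.633 in bts-3, 0.334 and 0.329 on +Fe, and 0.292 and 0.329 for the difference. In bts-3 the uptake list was called with the replicate block (0.0473), with the block in bts-3 only (0.0403) and without both arrays of number 3 (1.32e-05), with 1.44e-05 (without bts-3 -Fe replicate 3) to 0.975 over left-out arrays. The signalling list in bts-3 was at 0.0711 with arrays centred, and over left-out arrays at 3.28e-05 to 0.87, with 0.87 and 0.072 without bts-3 -Fe replicates 1 and 2 and 0.646 without bts-3 +Fe replicate 3. On +Fe the uptake list ran from 1.44e-05 to 0.0677 (without bts-3 +Fe replicate 2), and on -Fe the signalling list from 0.00161 (without bts-3 -Fe replicate 1) to 0.979.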

Other observations

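Of the added families, 5 are described here for bts-3 against WT on +Fe, besides the expansins, which had no call (23 genes, median -0.02, camera adjusted p = 0.437). No camera call was kept with an estimated correlation. The 23 TBL genes had a median log2 fold change of -0.44 (adjusted p = 1.97e-05, adjusted p = 0.424 with an estimated correlation), with no member past the threshold over the list alone. The 10 xyloglucan endotransglucosylases had a median of -0.62 (camera adjusted p = 0.0235, adjusted p = 0.468 with an estimated correlation, and 0.137 with the replicate block), with 2 lower over the list alone and XTH19 (-1.46) over all genes. The 6 tubulins had a median of -0.30 (camera adjusted p = 0.00888, adjusted p = 0.424 with an estimated correlation), with TUB5 (-1.07) past the threshold over all genes. Of 51 UDP-glycosyltransferases, 6 were higher and 2 lower over the list alone, and UGT87A2 (1.38) and UGT73B4 (1.49) over all genes (median 0.14, camera adjusted p = 0.00654, adjusted p = 0.424 with an estimated correlation). Of 13 glutathione transferases, GSTF3 and GSTU25 were higher and GSTU28 (-1.65) and GSTU26 (-1.02) lower over the list alone, without a call for the list (camera adjusted p = 0.653).

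Of the 32 serine carboxypeptidase-like genes, 9 had positive values in bts-3 against WT on +Fe and 10 on -Fe, 2 passed as lower over the list alone on each medium, and none passed over all genes. The list was called by camera on both media, with medians of -0.22 on +Fe (adjusted p = 0.0224) and -0.23 on -Fe (adjusted p = 0.0154), each with an adjusted p = 0.424 with an estimated correlation. With fry the adjusted p was 0.0485 on +Fe and 0.0485 on -Fe. With the replicate block the camera adjusted p was 0.0644 on +Fe and 0.0142 on -Fe. SCPL15 had log2 fold changes of -1.12 and -1.24 there, and of 1.48 on -Fe against +Fe in WT and 1.35 in bts-3, each past the threshold over the list alone and not over all genes. The 63 chloroplast-encoded genes had medians of -0.30 in WT on -Fe (camera adjusted p = 6.66e-12) and -0.12 in bts-3 (4.12e-06), with adjusted p = 0.424 and adjusted p = 0.519 with an estimated correlation. The bts-3 fall was uneven. The list mean was 10.64 on +Fe and 10.32 on -Fe in replicate 1, 10.63 and 10.65 in replicate 2, and 10.75 and 10.62 in replicate 3. These genes were not tested with single arrays left out. In bts-3 against WT their medians were 0.17 on +Fe (camera adjusted p = 0.000912, adjusted p = 0.702 with an estimated correlation) and 0.30 on -Fe (6.08e-16, adjusted p = 0.424 with an estimated correlation). The 2 shoot markers RCA and LHCB4.1 had medians of -1.18 in WT and -0.38 in bts-3 on -Fe against +Fe, and of -0.34 on +Fe and 0.47 on -Fe in bts-3 against WT. The cytochrome P450 gene CYP71B5 had a log2 fold change of 5.91 (SE 1.17) in WT, past the threshold over its list alone.

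AT5G07610, AT1G12890 and AT4G01870 were called both lower in bts-3 on -Fe and higher in bts-3 than WT on +Fe. Both comparisons use the bts-3 +Fe arrays, and independent lists would share 0.00526. Among as many top probe sets, simulated unchanged groups shared a mean of 0.73 and at most 2 over 100 draws. Those top probe sets were taken whether or not they passed the threshold. The draws therefore do not decide whether the shared bts-3 +Fe arrays gave the overlap. This overlap was looked for only after the calls were seen.

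Single measured members of the remaining short lists did not pass over the list alone. In WT -Fe against +Fe the values were 0.52 for CCS (copper), 0.28 for EIN3 (ethylene), -0.08 for AUR1 (dividing cells) and -0.27 for GI (clock).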
